A study of Homo sapiens with 16 samples.

How the data were processed

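Transcripts were measured in 16 cultures, 4 each of PECs alone, PECs from co-culture, MSCs from co-culture and MSCs alone, with Affymetrix HG-U133 Plus 2.0 arrays. RNA was extracted with TRIzol and RNeasy columns and labelled with biotin, 1 sample per array. The deposited values are log2 probe set summaries that the authors made with RMA, which includes background correction, quantile normalisation and median polish. The RMA version is not given, and neither is whether arrays of both cell types were normalised together. MSCs alone were grown in MSC GM medium, and PECs and co-cultures in EGM-2MV.

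The deposited columns hold 54675 probe sets with values between 3.34 and 15.0. The annotation names a single gene symbol for 41097 of them, several for 1801 and none for 11777. For each gene, the probe set with the highest mean over the 16 arrays was kept, which left 19740 genes. XIST, TSIX and Y-linked genes were removed before any fit. No filter on dim genes was applied. The number of arrays limits the precision, and no depth applies to array values.

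Each comparison was fitted with limma 3.58.1 (lmFit, eBayes) in R 4.3.3. PEC co-culture against PEC alone, MSC co-culture against MSC alone and MSC alone against PEC alone took 8 arrays each, and the MSC change minus the PEC change took 16. A gene was called changed at a two-sided Benjamini-Hochberg adjusted p under 0.05, and counts with at least a 2-fold change are given beside it. Overlaps between both co-culture comparisons were set against the number expected from independent lists. Correlations of changes were computed across genes.

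The 24 gene lists held 501 genes, of which 468 were measured here. They were endothelial, mesenchymal stromal, leukocyte and epithelial markers, smooth muscle contractile genes, mesenchymal transition regulators, fibrillar collagen and matrix genes, basement membrane genes, matrix proteases and inhibitors, and cell junction genes. The others were the Notch pathway, TGF-beta and BMP response genes, angiogenic and tip cell genes, inflammatory and leukocyte adhesion genes, interferon response genes, secreted stromal factors, osteogenic, adipogenic and chondrogenic genes, cell cycle genes, cholesterol synthesis genes, hypoxia and glycolysis genes, unfolded protein and amino acid stress genes, immediate early and heat shock genes, shear and KLF-linked endothelial genes, and ribosomal protein genes. Lists overlap, as TWIST1, SOX9, DCN, IL6 and others stand in more than 1. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Members were also adjusted over the list alone. With an estimated correlation, the calls of mesenchymal stromal markers, fibrillar collagen and matrix genes, osteogenic, adipogenic and chondrogenic genes and cholesterol synthesis genes held in PECs, and no call held in MSCs.

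Named genes followed a rule. For each co-culture comparison it took the 7 largest rises and the 7 largest falls among called genes whose groups did not overlap and whose higher group mean was over 6 on the log2 scale. It added the 3 called members with the largest change from each list that passed camera or had at least 3 called members, and PECAM1 and TIMP3. For the interaction and for MSCs against PECs cultured alone it took the 4 largest differences in each direction. HLA genes, common copy-number polymorphic genes such as GSTM1, immunoglobulin genes, LOC, orf, FLJ and KIAA names and probe sets without a single gene symbol were passed over. The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. Genes beyond both pure cultures, called in the same direction against each (the other cell type in a fit of 16 arrays), were counted and the 7 farthest on each side named after seeing the data.

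The share of the other cell type in a co-culture array was estimated on the linear scale. For each marker at least 4-fold apart between the pure cultures, the level above the array's own cell type alone was divided by the difference between the pure cultures, and the median over markers was taken. Alternatives were replicate number as a block, eBayes with trend and robust options, quantile normalisation of the deposited columns, arrays centred on their median, genes in the lower 40 percent by mean left out, the mean of all probe sets per gene and every probe set tested. Others were probe sets ending in x_at or s_at left out, a pooled-variance test as a count only, 1 fit of 16 arrays, genes at least 4-fold apart between pure cultures left out, and the other cell type's share subtracted. List tests were repeated with fry and with an estimated correlation, and each replicate was left out in turn. For genes that changed alike in both cell types, the change was also computed that a mixture of the cells alone with that share of the co-cultured other cell type would give. After subtraction, values were divided by 1 minus the share, which raises genes nearly absent from the other cell type. Subtracted values were held at the 5th percentile of the array or above. Leaving out genes at least 4-fold apart keeps those with smaller differences, which the other cell type's share can still move.

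The fits were tested on simulated data with the residual spread of each comparison. Of genes given a log2 change of 0.5, the PEC fit called 79.1%, the MSC fit 80.6%, the fit of the pure cultures 86.6% and the interaction 64.2%. At a log2 change of 1, at least 98.5% were called. Changes of 0.5, 1 and 2 were given to 67, 67 and 66 of 19740 genes, with independent noise, fewer than were called in the real data. Of the calls, 2.1% were false in the PEC fit and 6.5% in the MSC fit. The pure cultures gave 5.9% and the interaction 6.9%. Shares were also estimated from mixtures of the mean levels of the pure cultures, made without noise. They lay within 0.028 percentage points of the true share, which checks the formula but not the precision in real arrays. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

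Probe sets with several or no listed gene symbols were left out of the comparisons.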

Results

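Transcript levels were measured on 16 Affymetrix HG-U133 Plus 2.0 arrays, each hybridised with labelled material from 1 culture of human cells. Pulmonary endothelial cells (PECs), which line lung vessels, and mesenchymal stem cells (MSCs), stromal cells with osteogenic, adipogenic and chondrogenic potential, were grown alone or together and then separated. The 4 groups were PEC alone, PEC co-culture, MSC co-culture and MSC alone, and the labels call the 4 samples of each independent. Some labels describe the separation as magnetic bead selection with a CD31 antibody and others as FACS. The antigen of that antibody is PECAM1, so its level between sorted groups is no finding. The median probe set value of an array lay between 5.41 and 5.59 on the log2 scale. Correlations between arrays of a group across probe sets lay between 0.995 and 0.998. The number of arrays limits the precision. Changes are given as log2 differences ± SE with n = 4 per group, levels as log2 means ± SD with n = 4, and adjusted p-values come from limma.

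The endothelial and mesenchymal identities of the cells cultured alone stood far apart. MSCs expressed the collagen genes COL1A1, COL3A1 and COL12A1 and the Wnt ligand gene WNT5A, with log2 differences of 10.15 ± 0.061, 8.89 ± 0.13, 8.67 ± 0.073 and 8.42 ± 0.094 over PECs (adjusted p from 4.3e-12 to 5.6e-14). PECs expressed ITM2A, the fatty acid carrier gene FABP4, the annexin gene ANXA3 and the mannose receptor gene MRC1 at higher levels, with MSC minus PEC differences of -8.33 ± 0.053, -8.02 ± 0.081, -7.45 ± 0.084 and -7.43 ± 0.12. The junctional cadherin gene CDH5 had a level of 11.90 ± 0.054 in PECs and 4.54 ± 0.13 in MSCs. Of 19740 genes, 12500 differed at an adjusted p under 0.05, 5431 higher in MSCs and 7069 higher in PECs, and 2200 of them by at least 2-fold. The 20689 dim probe sets, with a mean under 5 and each group mean under 5.5, differed between the cell types by a median of -0.06 with a median absolute deviation of 0.19, against 0.08 and 0.09 within a cell type. All PEC arrays are labelled Set1 and all MSC arrays Set2, so cell type and array set are fully confounded wherever the 2 cell types were compared. The labels do not say whether both sets were normalised together, and centring each array on its median turned the split into 6592 higher in MSCs and 5619 higher in PECs.

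The effect of MSCs on PECs was asked by comparing PEC co-culture with PEC alone, both grown in the same medium. Collagen and other mesenchymal transcripts rose most in co-cultured PECs. COL1A1 (Entrez gene 1277) went from 3.80 ± 0.086 to 13.24 ± 0.094, a rise of 9.44 ± 0.065 (adjusted p = 9.2e-15). COL6A3, COL3A1, the enkephalin precursor gene PENK, WNT5A, COL1A2 and COL12A1 rose by 6.35 ± 0.12, 5.62 ± 0.13, 5.15 ± 0.14, 5.04 ± 0.12, 4.89 ± 0.11 and 4.87 ± 0.11, each with an adjusted p of 2.7e-09 or lower. After subtraction of the MSC share, 1 value per array for all genes, the COL12A1 change was 0.48 and no longer past the threshold. COL1A1, COL6A3, COL1A2, PENK, COL3A1 and WNT5A then changed by 9.36, 5.96, 4.29, 4.24, 4.01 and 3.14, each past it. COL3A1 probe sets other than the brightest changed by 3.62 and 4.22, and 2 dim ones by -0.09 and 0.16. The falls comprised MAMDC2 (-1.60 ± 0.072), the cytokine genes TNFSF18 (-1.58 ± 0.12) and LTB (-1.08 ± 0.069) and the survival gene BCL2A1 (-1.19 ± 0.081). They also comprised the chemokine genes CXCL8 (-1.19 ± 0.22) and CCL20 (-1.14 ± 0.15) and the urokinase gene PLAU (-1.09 ± 0.090), with adjusted p between 1.8e-07 and 0.0071. A dim LTB probe set changed by -0.04. PECAM1 stood at 12.66 ± 0.041 in PECs alone and 12.68 ± 0.026 after co-culture.

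**Figure D1:**
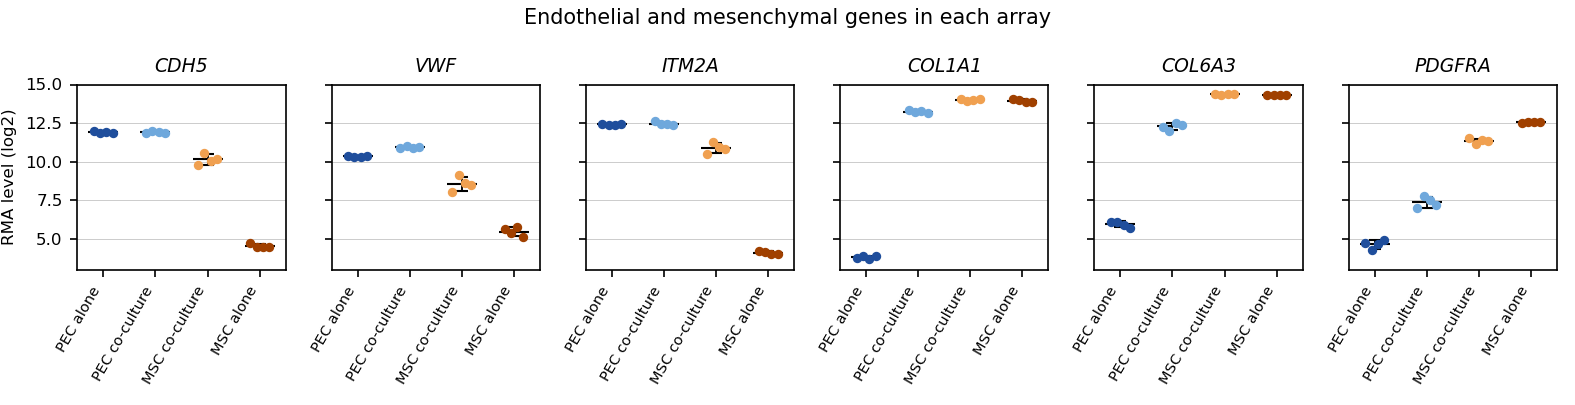
RMA levels (log2, vertical axis) of endothelial genes CDH5, VWF and ITM2A and mesenchymal genes COL1A1, COL6A3 and PDGFRA in each array of the 4 groups (horizontal axis). Points are arrays, black marks the mean with SD of 4 arrays. COL1A1 lay at 13.24 in PEC co-culture against 3.80 in PEC alone, and CDH5 at 10.14 in MSC co-culture against 4.54 in MSC alone.

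Among mesenchymal stromal markers, 19 of 25 measured members rose and 0 fell (21 and 0 adjusted over the list alone). Their median change was 1.76 (camera adjusted p = 3.2e-42; adjusted p = 0.0049 with an estimated correlation). Over 20 of these markers, the level in PEC co-culture corresponded to a median of 7.20% ± 1.47 (SD, n = 4 arrays) of the level in MSCs alone on the linear scale, after subtraction of the level in PECs alone. Over a wider set of 97 MSC-specific genes the median share was 2.22%, and it was 1.73% for the 55 of them with a level between 8 and 10 in MSCs. The share subtracted from PECs below is that of the 20 markers. Single markers lay between 0.899% for TWIST2 and 61.0% for COL1A1. Of the other COL1A1 probe sets, 1 gave 15.6%, 1 gave 17.8%, and the remaining ones, which differed little between the pure cultures, changed by 0.08 and -0.03 on the log2 scale. Among the 5 markers under 4-fold apart between the pure cultures 1 rose, and after subtraction of the MSC share 9 of the 25 rose and 7 fell. That share is the median over 20 of these same markers, so both rises and falls follow from the subtraction. Of fibrillar collagen and matrix genes, 19 of 26 measured members rose and 1 fell (21 and 2 adjusted over the list alone). The camera adjusted p was 1.1e-32, or an adjusted p = 0.0049 with an estimated correlation, and among the 12 members under 4-fold apart between the cell types 5 rose and 1 fell. The protease inhibitor gene TIMP3 rose by 1.85 ± 0.060 and the gelatinase gene MMP2 by 1.76 ± 0.083, or 0.75 with the MSC share subtracted, while PLAU fell. In the list of matrix proteases and inhibitors 8 of 22 measured members rose and 5 fell (9 and 5 adjusted over the list alone), and its camera adjusted p of 0.015 became an adjusted p of 0.18 with an estimated correlation.

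Cholesterol synthesis genes fell in co-cultured PECs. Of 17 measured members, 6 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 1.5e-07; adjusted p = 0.0073 with an estimated correlation). INSIG1, a sterol-regulated gene, changed by -0.67 ± 0.064, MSMO1 by -0.43 ± 0.055 and DHCR7, the enzyme of the last step to cholesterol, by -0.41 ± 0.056. With the 4-fold different genes left out, 6 of 16 members fell and 0 rose, and after subtraction of the MSC share 6 of 17 fell and 0 rose. Endothelial markers (7 rose, 1 fell of 25; 8 and 2 adjusted over the list alone) had a camera adjusted p of 0.0094, and an adjusted p of 0.065 with an estimated correlation. Risen members were the transcription factor gene SOX18 (1.02 ± 0.12), the multimerin gene MMRN1 (0.65 ± 0.10) and VWF (0.58 ± 0.051), and 7 lay above both pure cultures. TGF-beta and BMP response genes (10 rose, 2 fell of 23; 14 and 5 adjusted over the list alone), with TGFBI at 2.37 ± 0.055 and BMP4 at 0.73 ± 0.083, had a camera adjusted p of 1.0e-04 and an adjusted p of 0.065 with an estimated correlation.

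Of the shear and KLF-linked genes, 6 of 14 measured members rose and 3 fell (6 and 3 adjusted over the list alone). The aryl hydrocarbon receptor target CYP1A1 rose by 1.64 ± 0.074, TXNIP by 1.06 ± 0.068 and CYP1B1 by 3.29 ± 0.10. After subtraction of the MSC share the CYP1B1 change was -0.80. Its own share was 5.28%, below the 7.20% removed, so that fall follows from the subtraction. The camera adjusted p of the list was 0.0067, and the adjusted p was 0.065 with an estimated correlation. Inflammatory and leukocyte adhesion genes went both ways (5 rose, 5 fell of 25, and 7 and 6 adjusted over the list alone), at a camera adjusted p of 0.85. CXCL6 (2.03 ± 0.14, or 1.14 with the MSC share subtracted) and the inducible cyclooxygenase gene PTGS2 (0.998 ± 0.086) rose beside the falls of CXCL8 and CCL20. Osteogenic, adipogenic and chondrogenic genes (6 rose, 0 fell of 21; 7 and 1 adjusted over the list alone), led by CEBPD (1.15 ± 0.068), had an adjusted p of 2.6e-04, and an adjusted p of 0.032 with an estimated correlation. With the MSC share subtracted 1 member of that list rose and 3 fell. Secreted stromal factors (9 rose, 1 fell of 25; 10 and 2 adjusted over the list alone) included IGFBP3 (4.36 ± 0.17, or 2.75 with that share subtracted) and HMOX1 (-0.85 ± 0.078). With the share subtracted 5 of these factors rose and 8 fell, and over the 14 under 4-fold apart 3 rose and 1 fell (camera adjusted p = 0.69). Mesenchymal transition regulators (5 rose, 0 fell of 13; 6 and 1 adjusted over the list alone) included TWIST1 (2.99 ± 0.17, or 0.23 after the same subtraction). Interferon response genes (4 rose, 2 fell of 27; 6 and 3 adjusted over the list alone) included IFIT1 (0.94 ± 0.14) and IRF9 (0.61 ± 0.081), and unfolded protein and amino acid stress genes (3 rose, 2 fell of 21; 9 and 2 adjusted over the list alone) included DDIT4 (0.88 ± 0.067). These 4 lists had camera adjusted p of 0.0016, 0.026, 0.035 and 0.035, in the order named. With an estimated correlation the adjusted p were 0.12, 0.18, 0.36 and 0.18. The test of the mesenchymal transition regulators lost its call without PEC co-culture replicate 2. The interferon response genes lost theirs without PEC alone replicate 1 or PEC co-culture replicate 1 or 4, and the stress genes without PEC alone replicate 1 or PEC co-culture replicate 3. With the 4-fold different members left out, the camera adjusted p in PECs was 0.14 for mesenchymal stromal markers, 0.30 for TGF-beta and BMP response genes, 0.32 for stress genes and 0.40 for shear and KLF-linked genes. With the MSC share subtracted it was 0.13 for mesenchymal stromal markers, of which 20 set that share. It was 0.22 for transition regulators, 0.63 for proteases and inhibitors and 0.080 for interferon response genes. It was then 0.093 for secreted factors, 0.45 for osteogenic, adipogenic and chondrogenic genes, 0.46 for stress genes and 0.30 for shear and KLF-linked genes. TGF-beta and BMP response genes still passed with that share subtracted (11 rose, 2 fell, camera adjusted p = 0.0065). The interferon list did not pass with fry (adjusted p = 0.062).

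No camera test passed the threshold in PECs for smooth muscle contractile genes (3 rose, 0 fell of 15; 3 and 3 adjusted over the list alone), basement membrane genes (1 rose, 0 fell of 15; 2 and 1 adjusted over the list alone), cell junction genes (3 rose, 3 fell of 23; 3 and 3 adjusted over the list alone) or the Notch pathway (2 rose, 1 fell of 19; 3 and 1 adjusted over the list alone). The same held for angiogenic and tip cell genes (3 rose, 2 fell of 27; 5 and 2 adjusted over the list alone), cell cycle genes (3 rose, 0 fell of 35; 5 and 0 adjusted over the list alone), hypoxia and glycolysis genes (4 rose, 1 fell of 23; 4 and 1 adjusted over the list alone) and immediate early and heat shock genes (4 rose, 2 fell of 17; 4 and 5 adjusted over the list alone). The connexin gene GJA4 rose by 1.35 ± 0.072 and the apelin gene APLN fell (-0.91 ± 0.067). The cell cycle list passed without PEC co-culture replicate 1, 3 or 4, and the Notch list without PEC alone replicate 4 or PEC co-culture replicate 1 or 4. The Notch list also passed with replicate number as a block (adjusted p = 0.026), with fry (adjusted p = 0.0059), as the smooth muscle list did (adjusted p = 4.1e-04), and with the 4-fold different members left out (adjusted p = 0.030). The inflammatory list had a median of -0.05 and a mean of 0.05, and the immediate early list a median of -0.01 and a mean of 0.10. No member of the leukocyte, epithelial or ribosomal protein lists, with 15, 14 and 17 measured members, passed the threshold; their camera adjusted p were 0.85, 0.55 and 0.93.

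In all, 1380 of 19740 genes changed in co-cultured PECs at an adjusted p under 0.05, 820 up and 560 down, of which 111 by at least 2-fold, 101 up and 10 down. Without the 962 genes that differed at least 4-fold between the cell types, 738 changed, 377 up and 361 down. Centring each array on its median gave 592 up and 1101 down, and without PEC alone replicate 3 the count was 915.

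A comparison chosen after seeing the data counted genes whose PEC co-culture level lay beyond both pure cultures, past the threshold against each. The highest distance was that of the mitochondrial gene ND6, which rose by 2.12 ± 0.17 in PECs and 2.18 ± 0.094 in MSCs. The comparison gave 351 genes above both and 174 below both, 63 and 15 of them by at least 1.5-fold, and 223 and 451 with arrays centred on their median. Above both lay DEPP1, a FOXO target, at 9.50 ± 0.16 against 7.79 ± 0.075 in PECs alone and 7.77 ± 0.14 in MSCs alone. So did CYP1A1 at 10.12 ± 0.14, TNFSF10, which encodes the death ligand TRAIL, at 10.33 ± 0.26 and ANKRD55 at 8.88 ± 0.20. The other DEPP1 probe set, less bright, changed by 0.36 in PECs. CXCL8 lay below both, at 10.60 ± 0.58 against 11.78 ± 0.022 and 12.23 ± 0.080, as did the haem oxygenase gene HMOX1, at 8.73 ± 0.17 against 9.59 ± 0.040 and 9.73 ± 0.15, and PPP1R14A (-1.01 ± 0.13), AOX1, ARHGAP22, TMEM158 and RGS20. PTPRO lay above both (1.41 ± 0.16), though its 2 dim probe sets changed by -0.15 and 0.05. HINT3 also lay above both (1.52 ± 0.23), but its other probe sets gave changes of -0.16 and 0.09.

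The effect of co-culture on MSCs was compared between MSC co-culture and MSC alone, which differed in medium as well as in the presence of PECs, so the contribution of each is confounded. Endothelial transcripts rose most in MSC co-culture arrays. ITM2A went from 4.08 ± 0.097 to 10.89 ± 0.31 (Entrez gene 9452), a change of 6.82 ± 0.13 (adjusted p = 3.1e-09), and CDH5, SOX7, MRC1, MMRN1, TM4SF18 and ROBO4 rose by 5.61 ± 0.15, 5.43 ± 0.21, 5.43 ± 0.17, 5.27 ± 0.097, 5.08 ± 0.14 and 5.04 ± 0.15. After subtraction of the PEC share MRC1 changed by -0.34, SOX7 by 1.53 and TM4SF18 by 0.55, none past the threshold. ITM2A, MMRN1, ROBO4 and CDH5 then changed by 5.32, 4.56, 3.96 and 2.94, each past it. Their own shares of the level in PECs alone were 35.3%, 47.0%, 39.5% and 29.7%. The share removed averaged 26.4% and is a median over markers that include MMRN1, ROBO4 and CDH5. A gene with an own share above it keeps a rise by construction, so these rises are no evidence of expression by MSCs. The falls comprised CAMK2N1, a kinase inhibitor gene (-2.31 ± 0.048), the metallothionein gene MT1M (-2.22 ± 0.077) and the secretory GTPase gene RAB27B (-2.12 ± 0.12). They also comprised CORO2B (-2.04 ± 0.12), SHISA2 (-2.04 ± 0.057), the keratin gene KRT19 (-2.04 ± 0.097) and FLRT3 (-2.03 ± 0.089), with adjusted p of 1.6e-06 or lower. TIMP3 stood at 11.59 ± 0.22 against 11.45 ± 0.10, a difference that did not pass the threshold (adjusted p = 0.36). With the PEC share subtracted the change was 0.57 (limma adjusted p = 0.00038). The subtraction divides what is left by 1 minus the share, which by itself raises genes much lower in PECs. The 0.57 can therefore hold such rescaling and is no separate evidence of a rise. The 97 MSC-specific genes changed by a median of -0.56 in MSC co-culture, where dilution by the median share of PEC-specific genes alone would give -0.41.

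All 25 endothelial markers rose in MSC co-culture, with a median change of 3.41 (25 adjusted over the list alone; camera adjusted p = 2.3e-34; adjusted p = 0.071 with an estimated correlation). PECAM1, the antigen of the sort, was at 10.55 ± 0.29 against 5.70 ± 0.30. Over 24 of the markers, the level in MSC co-culture corresponded to 26.4% ± 6.96 (SD, n = 4 arrays) of the level in PECs alone on the linear scale, with 18.9%, 35.7%, 26.0% and 25.1% in replicates 1 to 4. Single markers lay between 11.6% for CLDN5 and 47.0% for MMRN1. None of the 25 lay above both pure cultures, and with the PEC share subtracted 5 rose and 7 fell (camera adjusted p = 0.22). That share is the median over 24 of these same markers. Rises and falls therefore follow from the subtraction, and this outcome tests nothing about the list. Mesenchymal stromal markers (2 rose, 12 fell of 25; 3 and 14 adjusted over the list alone) included a fall of PDGFRA (-1.21 ± 0.069) and a rise of PDGFRB (0.97 ± 0.081), at a camera adjusted p of 0.029. The adjusted p was 0.84 with an estimated correlation. On the deposited values the test pointed downward. With the PEC share subtracted 12 of these markers rose and 5 fell, with a median of 0.17, and the test passed upward (camera adjusted p = 0.0025). The subtraction rescales what is left, which by itself raises genes nearly absent from PECs, so this turn is no separate evidence of a rise. On the deposited values, without MSC co-culture replicate 2 or MSC alone replicate 1 the test lost its call. Over the 5 markers under 4-fold apart the camera adjusted p was 0.86.

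**Figure D2:**
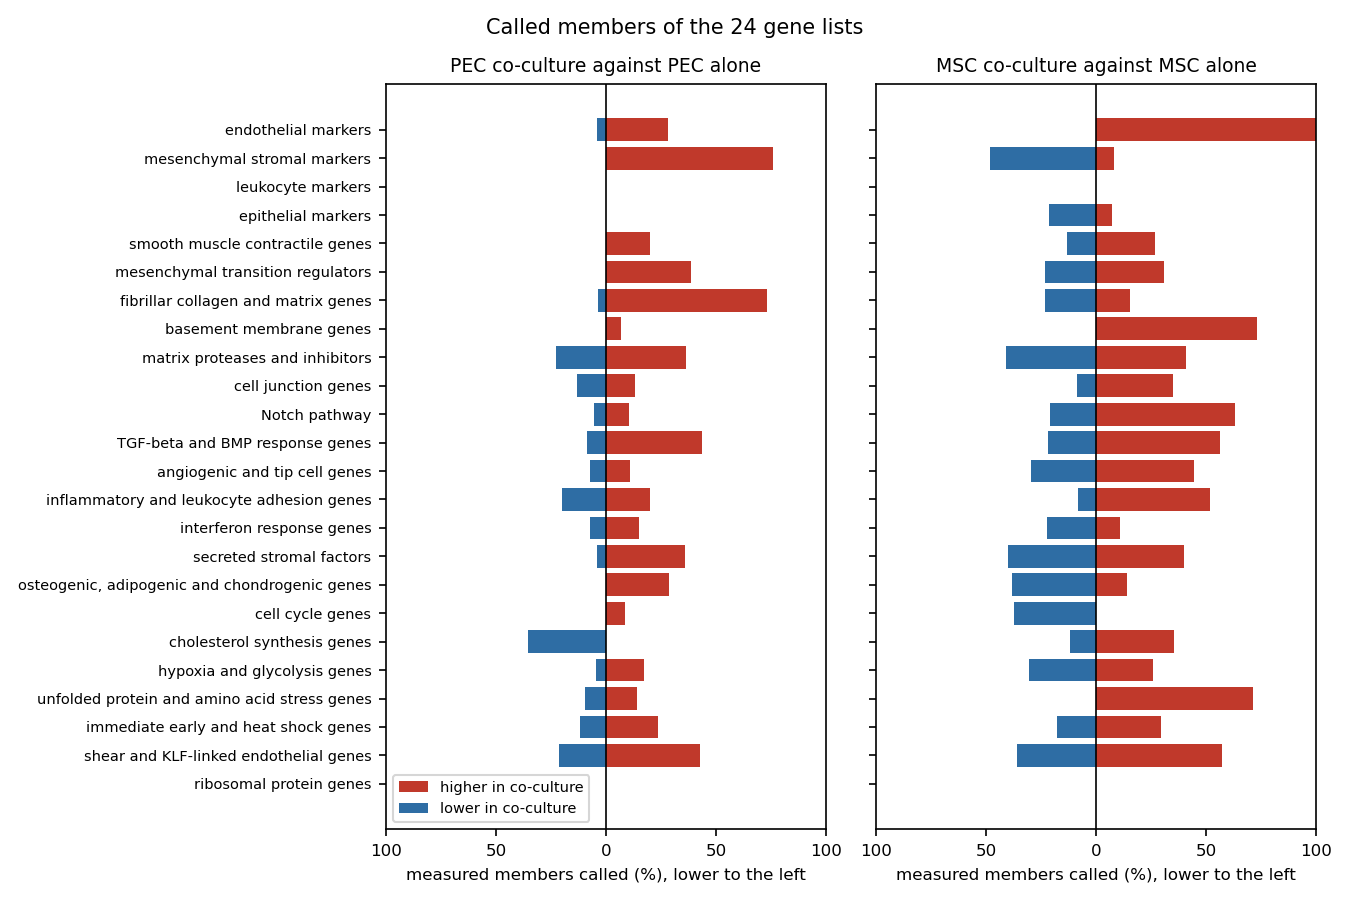
Percentage of the measured members of each gene list (vertical axis) called higher (red, to the right) or lower (blue, to the left) in co-culture at an adjusted p under 0.05 (horizontal axis, percent), for PECs on the left and MSCs on the right. In MSCs 25 of 25 endothelial markers were higher, and in PECs 19 of 25 mesenchymal stromal markers were higher.

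Unfolded protein and amino acid stress genes rose together in co-cultured MSCs. Of 21 measured members, 15 rose and 0 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.4e-09; adjusted p = 0.089 with an estimated correlation), and 14 lay above both pure cultures. With the PEC share subtracted 19 rose and 1 fell. The cystine transporter gene SLC7A11 changed by 1.30 ± 0.095, TRIB3 by 0.93 ± 0.058 and CHAC1, which encodes a glutathione-degrading enzyme, by 0.80 ± 0.073. Inflammatory and leukocyte adhesion genes (13 rose, 2 fell of 25; 15 and 3 adjusted over the list alone) included IL6 (2.45 ± 0.13), CCL2 (2.34 ± 0.12) and CXCL1 (1.10 ± 0.075), and 8 members lay above both pure cultures. The camera adjusted p was 2.5e-05, and the adjusted p was 0.071 with an estimated correlation. CCL2 was at 11.49 ± 0.10 in PECs alone, and its change was -1.98 after the endothelial share of each array was subtracted, when 10 members of the list rose and 10 fell (camera adjusted p = 0.40). Over the 17 members under 4-fold apart between the pure cultures 8 rose and 0 fell, and the test passed (camera adjusted p = 1.9e-04). That filter keeps members up to 4-fold higher in PECs, which the PEC share can still raise, so it cannot exclude carry-over. TGF-beta and BMP response genes (13 rose, 5 fell of 23; 13 and 6 adjusted over the list alone) included the activin subunit gene INHBA (2.42 ± 0.083), BMP4 (1.97 ± 0.17, or 0.97 with the PEC share subtracted) and ID3 (1.57 ± 0.058), and had a camera adjusted p of 4.5e-05. The adjusted p was 0.15 with an estimated correlation. Of the list 7 lay above both pure cultures. Cell cycle genes fell slightly (0 rose, 13 fell of 35; 0 and 16 adjusted over the list alone), with the replication helicase genes MCM2, MCM6 and MCM5 at -0.32 ± 0.041, -0.29 ± 0.054 and -0.28 ± 0.044 (camera adjusted p = 2.1e-04; adjusted p = 0.30 with an estimated correlation). After subtraction of the PEC share 0 rose and 4 fell, and the camera test did not pass (adjusted p = 0.33).

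The Notch pathway (12 rose, 4 fell of 19; 12 and 4 adjusted over the list alone) included the target gene HES1 (3.79 ± 0.12), the glycosyltransferase gene MFNG (3.35 ± 0.16) and the ligand gene JAG1 (2.74 ± 0.067), and had a camera adjusted p of 4.7e-07. The adjusted p was 0.051 with an estimated correlation. In MSC co-culture HES1 stood at 9.51 ± 0.088 and JAG1 at 12.73 ± 0.12, against 9.38 ± 0.058 and 12.55 ± 0.044 in PECs alone, whereas MFNG was at 8.50 ± 0.35 against 10.95 ± 0.028. After subtraction of the endothelial share, the changes of HES1, JAG1 and MFNG were 3.84, 2.79 and -1.09. The own share of MFNG, 17.3%, lay below the 26.4% removed, so its fall follows from the subtraction. Over the 11 Notch members under 4-fold apart 4 rose and 4 fell (camera adjusted p = 0.43), and with the share subtracted 8 of 19 rose and 4 fell (adjusted p = 0.015). A further HES1 probe set changed by 3.18 and a dim one by -0.05. Basement membrane genes (11 rose, 0 fell of 15; 12 and 0 adjusted over the list alone) included COL4A5 (3.33 ± 0.16) and COL18A1 (2.57 ± 0.17), both higher in PECs than in MSCs when cultured alone, and a COL4A5 probe set outside the s_at class changed by -0.10. The list had a camera adjusted p of 2.4e-09 and an adjusted p of 0.056 with an estimated correlation. With the PEC share subtracted 8 rose and 0 fell (camera adjusted p = 1.9e-06). Over the 12 members under 4-fold apart 8 rose and 0 fell as well (camera adjusted p = 2.1e-06), though the PEC share can still raise such members. Cell junction genes (8 rose, 2 fell of 23; 9 and 2 adjusted over the list alone), angiogenic and tip cell genes (12 rose, 8 fell of 27; 12 and 8 adjusted over the list alone) and shear and KLF-linked genes (8 rose, 5 fell of 14; 8 and 5 adjusted over the list alone) held endothelial genes such as PTPRB (4.42 ± 0.14), ANGPT2 (3.36 ± 0.11) and EDN1 (4.58 ± 0.12). With the PEC share subtracted these changes were 0.013, 0.51 and 3.03, the first 2 no longer past the threshold. The 3 lists had camera adjusted p of 4.7e-04, 0.029 and 0.018, and with an estimated correlation the adjusted p were 0.089, 0.098 and 0.097. Over the members under 4-fold apart between the pure cultures the medians of these 3 lists were -0.01, -0.07 and -0.15. With the PEC share subtracted none of the 3 passed (adjusted p = 0.94, 0.99 and 0.95). No ribosomal protein gene of 17 passed the threshold, though the camera adjusted p was 0.018 and the adjusted p was 0.62 with an estimated correlation.

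Secreted stromal factors went both ways in MSCs (10 rose, 10 fell of 25; 10 and 10 adjusted over the list alone), and 9 lay above both pure cultures, among them IL6, IL11 (1.76 ± 0.061) and IGFBP5 (3.54 ± 0.11). Over the 14 members under 4-fold apart 7 rose and 2 fell, and the test passed (camera adjusted p = 0.0038), as it did with the PEC share subtracted (10 rose, 8 fell; adjusted p = 0.019). Osteogenic, adipogenic and chondrogenic genes (3 rose, 8 fell of 21; 4 and 8 adjusted over the list alone) included a fall of the chondrogenic regulator SOX9 (-1.69 ± 0.073) and a rise of FABP4 (4.99 ± 0.21), which PECs expressed at 13.61 ± 0.021 and which changed by -1.53 after subtraction of the PEC share. Matrix proteases and inhibitors (9 rose, 9 fell of 22, and 9 and 9 adjusted over the list alone) included MMP10 (2.00 ± 0.082, or -0.83 after that subtraction) and the tissue plasminogen activator gene PLAT (-1.62 ± 0.078). The own share of MMP10, 8.11%, lay below the 26.4% removed, so its fall follows from the subtraction. Interferon response genes (3 rose, 6 fell of 27; 3 and 6 adjusted over the list alone) included IFI44L (-1.99 ± 0.098). Mesenchymal transition regulators (4 rose, 3 fell of 13, and 5 and 4 adjusted over the list alone) included SNAI2 (0.94 ± 0.074) and ZEB1 (-0.93 ± 0.043). With the PEC share subtracted their test passed upward (camera adjusted p = 0.026). Fibrillar collagen and matrix genes (4 rose, 6 fell of 26, and 5 and 8 adjusted over the list alone) included COL5A3 (2.17 ± 0.095) and DCN (-0.91 ± 0.11, or -0.47 with the PEC share subtracted). With that share subtracted 16 of the fibrillar genes rose and 2 fell (camera adjusted p = 7.7e-08), and of the 12 under 4-fold apart 4 rose and 1 fell (upward, adjusted p = 0.039). The subtraction by itself raises genes nearly absent from PECs, so the subtracted results are in part a rescaling. On the deposited values these 6 lists did not pass the camera test. With fry the secreted list passed upward (adjusted p = 0.0025). The transition, osteogenic and interferon lists passed downward with fry (adjusted p = 0.0025, 0.019 and 0.031). For the transition list that is opposite to the subtracted result. Nor did camera pass smooth muscle contractile genes (4 rose, 2 fell of 15; 5 and 4 adjusted over the list alone) or hypoxia and glycolysis genes (6 rose, 7 fell of 23; 6 and 9 adjusted over the list alone). The same was true of cholesterol synthesis genes (6 rose, 2 fell of 17; 7 and 3 adjusted over the list alone), immediate early and heat shock genes (5 rose, 3 fell of 17; 5 and 4 adjusted over the list alone), epithelial markers (1 rose, 3 fell of 14; 1 and 3 adjusted over the list alone) and leukocyte markers, of which none of 15 was called. Medians and means differed in sign for secreted stromal factors (-0.09 and 0.22), osteogenic, adipogenic and chondrogenic genes (-0.10 and 0.07), smooth muscle contractile genes (-0.05 and 0.06), epithelial markers (-0.06 and 0.03) and immediate early genes (0.06 and -0.02).

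In MSCs 5161 of 19740 genes changed at an adjusted p under 0.05, 2329 up and 2832 down, with 537 changed by at least 2-fold, 408 up and 129 down. Centring each array on its median gave 2004 up and 3728 down.

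The comparison with both pure cultures, chosen after seeing the data, placed 507 genes above both and 659 below both in MSC co-culture, 108 and 10 of them by at least 1.5-fold, and 464 and 842 with arrays centred on their median. The Wnt modulator gene DACT1 stood at 9.51 ± 0.27 against 6.06 ± 0.065 in MSCs alone and 4.75 ± 0.22 in PECs alone. IL6 stood at 10.23 ± 0.20 against 7.78 ± 0.24 and 7.83 ± 0.070, and INHBA at 13.32 ± 0.15 against 10.91 ± 0.11 and 11.84 ± 0.015. PDE3A, DCLK1, COL5A3 and the syndecan gene SDC2 rose by 2.31 ± 0.060, 2.22 ± 0.083, 2.17 ± 0.095 and 2.14 ± 0.087. CRYBG1 lay below both, at 7.40 ± 0.15 against 8.94 ± 0.13 and 8.56 ± 0.091, as did PKIA, ABCC3, AOX1, RGS20, GPAT3 (-0.77 ± 0.14) and LPXN (-0.76 ± 0.12); the ABCC3 probe set outside the s_at and x_at classes changed by 0.0013, and a dim LPXN probe set by 0.07. The other probe sets of IGFBP5 gave changes from 0.15 to 1.81.

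**Figure D3:**
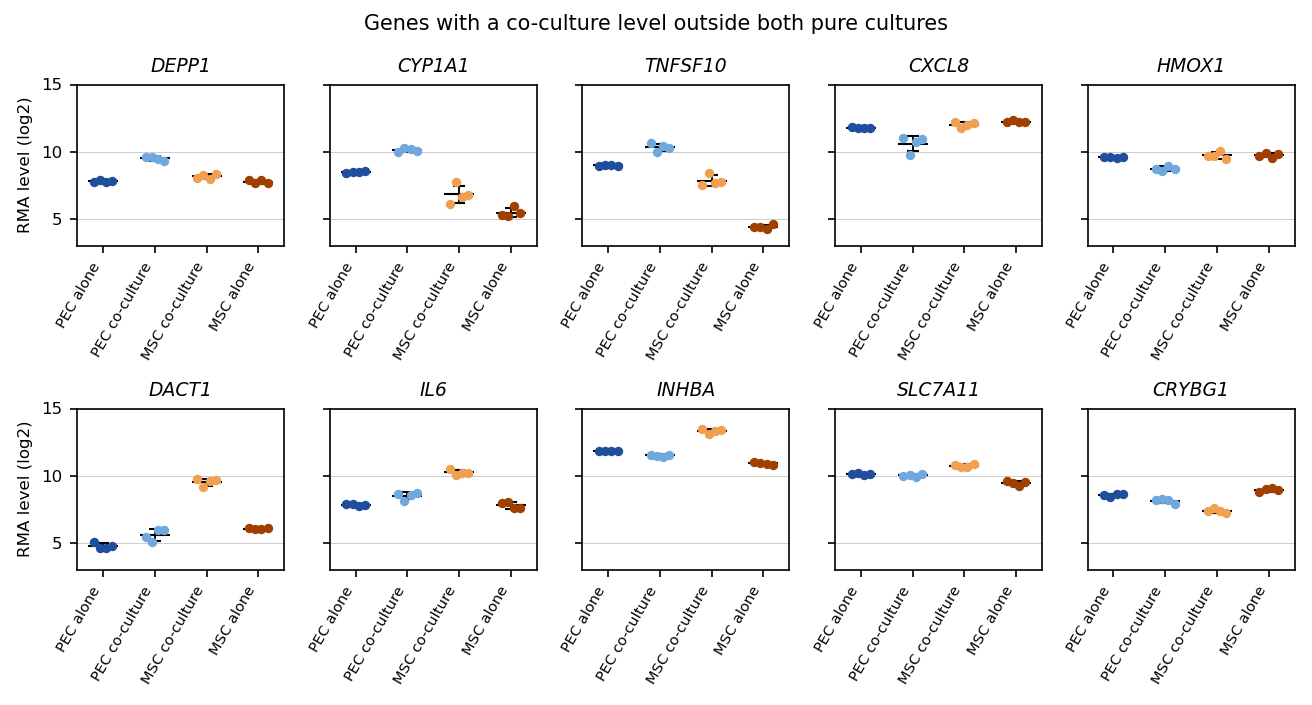
RMA levels (log2, vertical axis) in each array of the 4 groups (horizontal axis) for genes whose level in PEC co-culture (upper row) or MSC co-culture (lower row) lay beyond both pure cultures. Points are arrays, black marks the mean with SD of 4 arrays. DEPP1 lay at 9.50 in PEC co-culture, and DACT1 at 9.51 in MSC co-culture.

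The responses of both cell types were compared by the interaction of cell type and culture. The MSC change minus the PEC change was -9.36 ± 0.088 for COL1A1, -6.33 ± 0.14 for COL6A3, -5.86 ± 0.17 for COL3A1 and -5.47 ± 0.16 for PENK. It was 6.76 ± 0.15 for ITM2A, 5.61 ± 0.24 for SOX7, 5.60 ± 0.17 for CDH5 and 5.54 ± 0.18 for ANXA3, all with an adjusted p of 1.1e-11 or lower. Among stress genes, chosen here after their values were seen, the difference was 1.39 ± 0.12 for SLC7A11 and 1.20 ± 0.075 for TRIB3, which fell in PECs (-0.28 ± 0.051). Of the 21 members of that list the interaction passed the threshold upward for 9 and downward for 1. CXCL1, chosen in the same way, fell in PECs and rose in MSCs, with a difference of 1.89 ± 0.16 (adjusted p = 5.6e-08). CYP1A1, which rose in both, had -0.30 ± 0.32 (adjusted p = 0.57). It stood at 5.46 in MSCs alone and 6.81 in MSC co-culture, against 10.12 in PEC co-culture, so the PEC share can enter its MSC rise. In all, 4485 genes differed in response, 2150 with a more positive change in MSCs and 2335 with a more negative one, 705 of them by at least 2-fold, and centring each array on its median gave 2291 and 2012.

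Genes called in both cell types were counted per direction. AOX1 and RGS20 fell in both, with changes of -1.01 ± 0.073 and -0.85 ± 0.084 in PECs and -1.28 ± 0.057 and -1.16 ± 0.10 in MSCs, and PTGS2 rose in both. The other RGS20 probe set, less bright, changed by 0.0083 in PECs and -0.28 in MSCs. In all, 271 genes rose in both, against 96.7 expected from independent lists, and 104 fell in both, against 80.3. A further 243 rose in PECs and fell in MSCs, against 118 expected, and 229 fell in PECs and rose in MSCs, against 66.1. Dim genes entered the expectation, and every pair of directions exceeded it. The excess by itself is therefore no evidence of a shared response. Across genes, which are not independent replicates, the PEC and MSC changes had a Pearson correlation of -0.01 and a Spearman correlation of -0.09. The PEC change correlated at 0.415 (Spearman 0.207), and the MSC change at -0.690 (Spearman -0.507), with the MSC minus PEC difference of the pure cultures, with which each shares a group of arrays. Without the 4-fold different genes, 200 changed in the same direction in both cell types, and at least 2-fold in both, 15 did.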

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

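The splits of the arrays and the question of medium were planned, and the other tests of explanations reported here were chosen after the result was seen.

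Of 331 groups of 4 arrays of a named gene, 10 held an array whose gap to its neighbour exceeded Dixon's critical share of the group's range, while chance gives about 16.6. In PECs these were PECAM1 in PEC co-culture replicate 4 (0.912), LTB in PEC co-culture replicate 2 (0.896), DDIT4 in PEC co-culture replicate 3 (0.894), MYL9 in PEC alone replicate 2 (0.839) and ND6 in PEC alone replicate 2 (0.949), each the highest array of its group. In MSCs, CDH5 was highest in MSC alone replicate 1 (0.879) and DCN lowest in MSC alone replicate 2 (0.830). SHISA2 (0.843), ENO2 (0.894) and SNAI2 (0.899) were lowest in MSC co-culture replicate 2, the array with the highest endothelial share. With fewer such groups than chance gives, no array was left out on this ground.

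The responses of PECs and MSCs differed by the interaction test for 4485 genes. The largest differences, MSC change minus PEC change, were -9.36 for COL1A1, -6.33 for COL6A3, -5.86 for COL3A1 and -5.47 for PENK, and 6.76 for ITM2A, 5.61 for SOX7, 5.60 for CDH5 and 5.54 for ANXA3. Each of these 8 genes marks the other cell type in the culture where it rose, so the shares of the other cell type in the sorted arrays enter these differences. Of 11721 probe sets with no listed gene that were fitted, 69 changed in PECs (40 up, 29 down) and 444 in MSCs (226 up, 218 down), in data outside the comparisons.

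Other splits of the same arrays were counted. For PECs, MSCs and the pure cultures, 1380, 5161 and 12500 genes were counted. Only 1 of the 35 splits of 8 arrays, the real one, gave as many in each case, and the highest count of any other split was 0. That share, 0.029, is the smallest that 35 splits can give. Every other split mixes both groups, which widens the spread within each part, so the counts of 0 do not exclude chance. For the pure cultures the real split is also that of the Set1 and Set2 labels. For the interaction, 1 of 100 drawn splits, the real one, reached 4485 genes, and the highest other gave 3371. That split kept 3 of the 4 PEC arrays and all 4 MSC arrays of a culture together, which is close to the real grouping.

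Endothelial transcripts in MSC co-culture arrays were weighed against the sort, since a CD31 selection would remove PECs. A scale difference between arrays was weighed with the 20689 dim probe sets, which shifted by a median of -0.030. The endothelial list moved by a median of 3.41. RMA includes quantile normalisation, and these probe sets were chosen to be dim in every group. A small shift was therefore largely set in advance, and this test cannot decide on scale. PEC RNA carried through the sort is a candidate explanation: 97.7% of 87 PEC-specific genes were highest in the same array, MSC co-culture replicate 2, against 25% by chance, and all 87 (100%) lay above 5% of their level in PECs alone. Their median share was 24.8%, and 94.8% of 97 MSC-specific genes were lowest in that array. An endothelial programme taken up by a share of the MSCs cannot be told apart from it, because such cells would give the same levels at the same share.

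The COL1A1 level in PEC co-culture arrays corresponded to 61.0% ± 3.97, 15.6% ± 3.42 and 17.8% ± 7.53 (SD, n = 4) of the level in MSCs alone by its 3 responding probe sets, against a median of 7.20% over the mesenchymal markers. MSC RNA carried through the sort at the share of other MSC-specific genes may account for it, but the least bright of these probe sets, at 17.8%, lay by less than 1 SD above 13.9%, the share that 1 in 40 of 30 like-bright genes would exceed, so the test left it open; that margin was also set after the result was seen. By the brighter probe sets the share exceeded the same limit, 10.1% and 10.2%, by over 1 SD, from 2 and 9 like-bright genes. Compression of bright signals cannot be told apart from it either, because the same 13.9% limits that test. COL1A1 expression by PECs themselves was not tested and stays open.

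Unfolded protein and amino acid stress genes rose in MSC co-culture arrays. Carry-over of PEC RNA is argued against as the whole cause, because 14 of 21 members lay above both pure cultures, which no mixture of the pure cultures would give, and all 14 also lay above PEC co-culture. PEC and MSC arrays carry different set labels, and with arrays centred on their median the count was 14 again. The change of medium cannot be told apart from a response to PECs, since MSCs alone had another medium. In PECs, whose medium was the same in both groups, the list had a median change of 0.13 and 3 members rose and 2 fell, which does not bear on MSCs. A response of MSCs to PECs therefore stays among the open explanations.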

How the results depend on the processing

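Counting genes past the threshold against both pure cultures was chosen after seeing the data, and the other alternatives were planned. Replicate number as a block gave 983 genes for PECs, 4511 for MSCs, 12105 for the pure cultures and 4337 for the interaction. Deviations of same-number arrays from their group means correlated across genes at -0.16 to 0.02 in PECs and -0.09 to 0.11 in MSCs. For MSC co-culture replicates 1 and 2 the best match was the MSC alone array of the same number, but not for replicates 3 and 4. In PECs no array was matched best by its own number, so pairing by number stayed unsettled. Requiring at least a 2-fold change, a stricter rule, gave 111, 537, 2200 and 705, and 15 for genes changed in both cell types. Centring arrays on their median left 34.97% of PEC changes upward instead of 59.4%, 34.96% of MSC changes instead of 45.1% and 54.0% of the pure-culture differences instead of 43.4%. Without the genes 4-fold apart between pure cultures, 738 genes changed in PECs and 200 in both cell types. Subtraction of the other cell type's share gave 2050 in PECs and 6228 in MSCs. Past the threshold against both pure cultures were 525 genes in PECs and 1166 in MSCs, 78 and 118 at least 1.5-fold from both, and 66 and 118 with centred arrays.

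Of 76 values of genes named for PECs, 74 kept their direction and side of the threshold with centred arrays (all but NUSAP1 and CCNB2) and 70 with the replicate block (all but UBE2C, NUSAP1, CCNB2, HES1, JAG1 and MYL9). Of 84 for MSCs, 84 did in both cases. With the other share subtracted 62 and 65 did.

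Leaving out each array in turn gave 915 to 1840 genes in PECs, the lowest without PEC alone replicate 3 and the highest without PEC co-culture replicate 2. The ranges were 4260 to 4711 in MSCs, 11835 to 12134 for the pure cultures and 3940 to 4921 for the interaction, with fewer arrays per fit. Camera passed 10 to 13 lists in PECs and 11 to 12 in MSCs. With an estimated correlation 4 of 12 lists passed in PECs and 0 of 12 in MSCs, where fry gave 16; without the members 4-fold apart 5 passed in PECs, with fewer members tested.

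Directions reversed as follows, and beyond the subtraction itself the cause was not tested. The share subtraction by itself raises genes nearly absent from the other cell type. It also lowers genes whose own share lies below the one removed. Own shares were 3.62% for ROBO1, 2.76% for RUNX2 and 5.28% for CYP1B1, against 7.20% removed from PECs. They were 6.26% for MMP1, 8.11% for MMP10, 17.3% for MFNG, 23.0% for PECAM1, 24.4% for KDR and 25.1% for MRC1, against 26.4% removed from MSCs. The falls of these genes follow from the subtraction. With x_at and s_at probe sets left out, so that other probe sets stood for the gene, changes were -0.087 for COL3A1, -0.14 for HES1 and -0.16 for ACAN in PECs, -0.10 for COL4A5, -0.055 for HES1, -0.13 for ACAN, 0.0013 for ABCC3 and 0.068 for LPXN in MSCs, and 0.49 for COL3A1 in the interaction. With the other cell type's share subtracted, in PECs 7.20% against a median of 2.22% over 97 MSC-specific genes, PEC changes were -0.61 for ROBO1, -2.34 for VEGFA, -1.45 for EGR1, -0.21 for RUNX2, -0.80 for CYP1B1, -1.51 for TAGLN and -0.082 for MYL9. MSC changes were then -1.63 for PECAM1, -0.34 for MRC1, -0.68 for KDR, -0.84 for LAMA5, -1.98 for CCL2, -0.88 for OAS1, -1.06 for RIGI, -0.83 for MMP10, -1.26 for MMP1, -1.09 for MFNG and -1.53 for FABP4. With members 4-fold apart left out, list medians were -0.044 for mesenchymal transition regulators and 0.050 for matrix proteases and inhibitors in PECs, and -0.0076 for fibrillar collagen and matrix genes and -0.15 for shear and KLF-linked genes in MSCs. In MSCs the medians of cell junction genes (-0.012) and angiogenic and tip cell genes (-0.074) turned as well, while their tests stayed upward. The median of mesenchymal stromal markers in MSCs turned to 0.0029, while the test of that list stayed downward. With the share subtracted, medians in PECs were -0.13 for mesenchymal transition regulators, -0.054 for secreted stromal factors, -0.011 for matrix proteases and inhibitors and -0.0096 for osteogenic, adipogenic and chondrogenic genes. In MSCs they were 0.17 for mesenchymal stromal markers, -0.17 for inflammatory genes, -0.11 for cell junction genes, -0.18 for angiogenic genes and -0.13 for shear and KLF-linked genes. These lists had passed camera, and 9 medians of lists that had not turned too. With the 4-fold members left out it was, for the proteases and the fibrillar collagens, the direction of the camera test that turned, downward and upward. Signals near background limit dim probe sets, such as those left for COL3A1 and HES1.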

Other observations

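The genes and counts given here were chosen after their values were seen. Genes under 4-fold apart between the pure cultures, called in the same direction in both cell types and changed by at least 1.5-fold in each, numbered 18 up and 8 down. The falls, PEC change before MSC change, included -1.01 and -1.28 for the aldehyde oxidase gene AOX1, -0.91 and -1.31 for ARHGAP22, -0.89 and -1.57 for TMEM158, -0.85 and -1.16 for RGS20 (its other probe set 0.0083 and -0.28) and -0.84 and -0.70 for the chromatin protein gene HMGA2. The mitochondrial gene ND6 rose by 2.12 and 2.18. PTGS2 rose by 0.998 and 0.92 and PLA2G4A by 0.88 and 0.78. In MSCs, RNA of co-cultured PECs at the 26.4% share would give changes of 1.60 for ND6, 0.45 for PTGS2 and 0.62 for PLA2G4A. For 5 of the 18 rises it would give more than was observed in MSCs: 1.49 against 0.73 for SEMA3G, 1.16 against 0.70 for ZNF117, 0.94 against 0.69 for RPGR, 1.20 against 0.83 for PKHD1L1 and 1.04 against 0.84 for LRRC1. For PIM3 it would give 0.70 against 0.77. COL5A3 rose by 1.05 and 2.17, DACT1 by 0.85 and 3.45 and IL6 by 0.67 and 2.45. These 3 genes stood at 9.98, 9.51 and 10.23 in co-cultured MSCs, against 6.10, 4.75 and 7.83 in PECs alone. In PECs, RNA of co-cultured MSCs at the 7.20% share would give changes of 0.99, 1.53 and 0.39, and at 2.22% it would give 0.38, 0.66 and 0.13. PECs had the same medium in both groups, and MSCs did not. NOTCH3 rose by 0.70 and 1.32, but its other probe set changed by 0.20 and -0.05, and the 7.20% share of co-cultured MSCs would give 0.68 in PECs, or 0.24 at 2.22%.

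In PEC co-culture arrays, 97 MSC-specific genes had a median share of 2.22% of their level in MSCs alone. The median share was 1.73% for the 55 genes with a level between 8 and 10 in MSCs alone and 7.02% for the 11 genes between 12 and 15. In MSC co-culture arrays, 87 PEC-specific genes had a median share of 22.9% in the lower of these ranges, with 45 genes, and 21.0% in the higher, with 3 genes.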
